A study of Mus musculus with 6 samples.

How the data were processed

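RNA was measured by sequencing in 6 libraries of primary mouse hepatic stellate cells, the retinoid-storing pericytes of the liver. Per the labels' protocols, the cells came from collagenase and pronase perfusion, a Nycodenz gradient and removal of macrophages with Cd11b microbeads, attached for 4 h, were cultured for a further 14 h with 10% serum, and were collected at day 1. The labels describe male C57BL/6 mice of 24 weeks. Per the submitters' processing notes, RSEM and the mm10 build were used; the RSEM version is not given in the sources used here.

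Each deposited file holds 1 library, with an NCBI gene identifier, RefSeq transcripts, a length, an expected count and an FPKM value per gene, per the file headers. The expected counts are the authors' deposited estimates of reads per gene and need not be whole, per the file headers. The FPKM values were computed by the authors as fragments scaled by gene length and library depth, per the file headers, and are deposited to 2 decimals with 0.01 as the lowest value. The files list no value of 0, so a gene missing from a library and present in another was set to 0, which filled 12658 cells. In all, 17909 identifiers were listed in at least 1 library, and 17857 were named through the reference gene tables of GRCm38, the assembly of which mm10 is another name. The other 52 identifiers are unnamed here. None of the 26 names on a list of mitochondrially encoded genes appeared in the files.

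Total expected counts were between 11961726 and 12423220 per library. Intervals and floors below cover counting error only, because reads without molecular identifiers are not independent molecules. A fold against a group with no counts was computed against a floor of 3 counts over the group and is given as a lower bound. Where a group held 1 to 3 counts, the ratio of group sums is given with a 95% exact interval. These bounds, ratios and intervals were scaled by the groups' summed library totals after TMM adjustment, so they differ from the ratios of the raw counts.

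Libraries were grouped by the genotype in their labels. Within groups, pairs of libraries had chi-square values per degree of freedom of 5.44 to 15.3 in HAS2_Tg and 2.09 to 3.07 in Has2_KO, over genes with at least 20 counts in the pair, so they differed by more than sampling noise and were counted as 3 libraries each. The groups share no replicate numbers, so no pairs were formed. Expected counts were rounded to whole numbers, filtered with filterByExpr, scaled by TMM and tested with edgeR's robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment at 0.05. The contrast was HAS2_Tg minus Has2_KO, so a positive log2 fold change means a higher level in the transgenic libraries. The standard error (SE) is the size of the log2 fold change divided by the square root of the F statistic. CPM values are TMM-normalised. Fixed gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Library values were compared by exact permutation, two-sided, for which 0.1 is the smallest p that 3 against 3 libraries allow.

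Genes were named by a rule fixed before the data were examined. It took Has2, the 12 largest changes in each direction among called genes with at least 5 CPM in the higher group, no overlap between groups and a symbol that is not a predicted name, up to 3 members per list by adjusted p, and the 3 smallest adjusted p in each direction. Some genes that the rule takes are not reported here. Other names were chosen after their values were seen. The 34 lists covered hyaluronan, Notch, stellate cell, matrix, signalling, metabolic and stress genes, and markers of other liver cell types.

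The alternatives were DESeq2 size factors, total counts, upper-quartile factors, no low-count filter, a stricter filter (1 CPM in every library of a group and a mean of 5 CPM), the DESeq2 Wald test, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of 1 in 3 libraries, limma with no filter, each library left out, an adjusted p of 0.01, and a test against a fold of 1.5. Fits without the sex chromosomes, without the marker-list genes and without genes named as pseudogenes were added after seeing the data.

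The script was tested on simulated counts for the HAS2_Tg against Has2_KO comparison, with 200 genes changed, of which 195 passed the filter among 12853 genes. It recovered 22% of genes changed 1.25-fold, 76% at 1.5-fold, 91.8% at 2-fold and 100% at 4-fold. Of 152 calls, 12 were unchanged genes (7.89%). In the same simulation the 1 changed list was called and 0 of 30 unchanged lists were. Its genes were drawn independently, so it did not test lists whose members are correlated. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.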

Results

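The series compared day 1 cultures of primary mouse hepatic stellate cells from 2 genotypes. In the HAS2_Tg group (replicates 4, 5 and 6) a human HAS2 transgene was driven by the alpha smooth muscle actin promoter, and in the Has2_KO group (replicates 7, 8 and 9) Has2 was deleted in stellate cells with Lrat-Cre. Has2 encodes a hyaluronan synthase, an enzyme that makes the matrix polysaccharide hyaluronan. Total expected counts were 12024968, 11961726 and 12231327 in the transgenic libraries and 12364822, 12423220 and 12378445 in the knockout libraries. The transgenic libraries listed 15372, 15472 and 15396 genes and the knockout libraries 16131, 16218 and 16207. Gene identifier 19791, which the reference does not name, took 1.59% of the counts of HAS2_Tg replicate 4 and at most 0.156% in any other library.

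Has2, the targeted gene, had 847, 889 and 835 counts in the transgenic libraries and 1 count in each knockout library, which goes with the knockout label. It lies on the minus strand of chromosome 15 from 56665627 to 56694546 (GRCm38). Its level was 75.5 ± 2.32 CPM (SD, n = 3) in HAS2_Tg, and the ratio of group sums, scaled by TMM-adjusted library totals, was 992.5 with a 95% exact interval of 339.2 to 4816 (edgeR adjusted p = 2.15e-14). Reads of the human transgene counted to mouse Has2 only as far as they aligned there, and no wild-type group was analysed here, so this level does not check the transgenic label.

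Myh11 and Igfbp3 led the genes higher in HAS2_Tg by adjusted p beside Has2, and most tested members of the NF-kB cytokine, macrophage marker and sinusoidal endothelial marker lists were higher in Has2_KO. Myh11, smooth muscle myosin heavy chain, stood at 1270.4 ± 127 CPM in HAS2_Tg and 108 ± 6.57 CPM in Has2_KO (SD, n = 3; log2 fold change 3.55, SE 0.10). Igfbp3, an insulin-like growth factor binding protein, was 1552 ± 183 against 107 ± 6.33 CPM (3.87, SE 0.10). In the other direction Ccl6, a chemokine, was 1.06 ± 0.10 against 245 ± 12.3 CPM (log2 fold change -7.84, SE 0.13, edgeR adjusted p = 5.59e-15), and Cdh5, the endothelial cadherin, was 1.76 ± 0.47 against 402 ± 17.5 CPM (-7.83, SE 0.13). Of 13014 genes tested, 5298 differed between the groups, 2625 higher and 2673 lower in HAS2_Tg. Changes of at least 2-fold were mostly lower in HAS2_Tg, with 1030 of 1461 genes.

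The remaining genes with the largest positive changes were Ifi202b, Rpl34-ps1, Stbd1, Ptger3, Angpt1, Kcnk3, Adra1d, Ptchd4 and Tmem119. Stbd1, a starch-binding protein, had a log2 fold change of 4.12 (SE 0.13), Ptger3, a prostaglandin E2 receptor, 4.03 (SE 0.23), Angpt1, a ligand of the Tie2 receptor, 3.96 (SE 0.14) and Adra1d, an alpha-1 adrenergic receptor, 3.66 (SE 0.18). Kcnk3, a potassium channel, reached 3.74, Ptchd4 3.44 and Tmem119 3.31. Ifi202b, an interferon-inducible gene, had 13.5 CPM in HAS2_Tg, and its scaled ratio of group sums was 267 with a 95% exact interval of 73.5 to 2211. The cause of the Ifi202b difference was not tested, and the list of interferon-stimulated genes did not pass (camera adjusted p = 0.289). The value of Rpl34-ps1 (5.83) is uncertain, as its sequence resembles that of Rpl34. Its symbol is that of a pseudogene, although the reference lists it as protein coding. Several of the genes with the largest negative changes had no count in any HAS2_Tg library. St8sia4, a polysialyltransferase, was at least 109.7-fold lower, Mup19 79.4-fold, Adgrg3 72.2-fold and Gpihbp1, the lipase anchor of capillaries, 67.4-fold lower, each as a scaled lower bound against 3 counts over the group. The same bound was 63.3-fold for the Kupffer cell lectin Clec4f and 58.7-fold for Lfng, a glycosyltransferase that modifies Notch. The Mup19 value is uncertain because its reads can be shared with other Mup genes, and that of the pseudogene Atp6v0c-ps2 (-10.77) because they can be shared with Atp6v0c (2.35, chosen after its value was seen). Lcn2, lipocalin 2, was lower in HAS2_Tg by a scaled ratio of 576 (95% exact interval 159 to 4764).

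Hyaluronan genes other than Has2 were mostly lower in HAS2_Tg. Of 24 tested members of the hyaluronan synthesis, breakdown and binding list, 6 rose, Has2 among them, and 13 fell (median log2 fold change -0.58, camera adjusted p = 6.22e-05, and 0.0458 with an estimated correlation). The scavenger receptor Stab1 fell by 5.25 on the log2 scale (SE 0.12) and Cemip2, described as a cell-surface hyaluronidase, by 3.71 (SE 0.12). Cd44, the main hyaluronan receptor, had -1.11 and Tlr4 -0.89, both chosen after their values were seen. Without genes of the marker lists, a fit added after seeing the data, the list's adjusted p was 0.166; Stab1 is also on the endothelial list. Of 17 UDP-sugar supply genes, which provide the precursors of hyaluronan, 2 rose and 6 fell, including the hexosamine enzymes Gfpt2 (-1.58) and Gfpt1 (-0.55) and the hexokinase Hk2 (-1.20), and the list did not pass (camera adjusted p = 0.254).

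Notch genes moved both ways. Of 33 tested, 11 rose and 11 fell (median -0.12, camera adjusted p = 0.66). Notch3 (1.73, SE 0.10), Heyl (1.72, SE 0.13), Hey1 (1.76) and Hey2 (1.11) rose, while the receptor Notch4 fell by 1.73 (SE 0.12). Nrarp (-5.01), the ligand Dll4 (-1.36), Rbpj (-0.68), Notch2 (-0.32) and Mfng, which had no count in any HAS2_Tg library, were also lower. Notch1 (0.34) and Hes1 (0.22) were slightly higher. Hey1, Hey2, Nrarp, Mfng, Dll4, Rbpj, Notch2, Notch1 and Hes1 were chosen after their values were seen. Endothelial (median -5.73) and macrophage (median -5.80) markers fell in the same libraries as Notch4, Dll4, Nrarp and Mfng.

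Stellate cell genes were mostly higher in HAS2_Tg, both those of activation and those of identity. Of 36 activation genes, 26 rose and 8 fell (median 0.71, camera adjusted p = 2.48e-09, and adjusted p = 0.0844 with an estimated correlation). Acta2, alpha smooth muscle actin, was 5904 ± 708 against 1196 ± 13.7 CPM (log2 fold change 2.30, SE 0.10, n = 3), Tagln 2.03 (SE 0.09) and Myl9, a myosin light chain, 2.39 (SE 0.09). The vascular smooth muscle markers Myh11 (3.55), Lmod1 (2.41) and Notch3 (1.73) rose with them, although their list split 6 and 6, and macrophage (median -5.80) and endothelial (median -5.73) markers fell in the same libraries. Among the 8 that fell were Spp1 (-4.44), Timp1 (-1.10) and Tgfb1 (-0.57), chosen after their values were seen. Of 34 quiescence and identity genes, 20 rose and 6 fell (median 0.42, camera adjusted p = 3.61e-07, and 0.0458 with an estimated correlation). Colec11 and Colec10, collectins, had 2.83 (SE 0.08) and 2.79 (SE 0.09), and Lrat, which esterifies retinol, 1.98 (SE 0.08). Reln had -0.01 (SE 0.10) and Dcn 0.37 (SE 0.09), chosen after their values were seen.

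Collagen and basement membrane genes rose in 19 of 25 cases and fell in 3 (median 0.58, camera adjusted p = 2.20e-06, and adjusted p = 0.16 with an estimated correlation). Col8a1 had 1.95 (SE 0.08) and Col14a1 1.39 (SE 0.08), while Col18a1 fell by 2.32 (SE 0.09). Among matrix proteases and inhibitors 7 of 24 rose and 10 fell (camera adjusted p = 2.93e-05, and adjusted p = 0.0933 with an estimated correlation). The metalloproteases Mmp3, Mmp13 and Mmp12 had -6.74, -6.57 and -6.14, each with an SE of at most 0.15. Macrophage markers (median -5.80) moved with these proteases. YAP and TEAD targets rose in 12 of 21 cases and fell in 7 (camera adjusted p = 0.000351, and adjusted p = 0.16 with an estimated correlation), with Tgfb2 at 1.81 and Crim1 at 1.17 beside Igfbp3. Wnt pathway genes rose in 12 of 28 cases and fell in 5 (camera adjusted p = 0.0039, and adjusted p = 0.0902 with an estimated correlation), with Dkk3 at 2.45, the receptor Fzd2 at 2.10 and the Wnt antagonist Nkd1 at 1.34. The median of the Wnt list was 0.24, and 0.07 with total counts, so its size depends on scaling. TGF-beta and BMP genes moved both ways, 12 up and 11 down of 35 (median -0.08, mean -0.17, camera adjusted p = 0.533 with direction up). The ligand Tgfb3 was 660 ± 55.9 against 90.6 ± 3.74 CPM (2.86, SE 0.09), and Inhbb had -3.41.

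The NF-kB list was lower in HAS2_Tg almost throughout. Of 33 NF-kB cytokines and chemokines, 31 fell and none rose, with Cxcl10 (0.04) and Irf1 (-0.16), named after their values were seen, not passing (median -1.79, camera adjusted p = 7.60e-44, and 0.00599 with an estimated correlation). The monocyte chemokine Ccl2 was 31.9 ± 0.94 against 603 ± 5.18 CPM (-4.24, SE 0.08), and the neutrophil chemokines Cxcl5 and Cxcl2 had -6.44 and -4.13. Kupffer cell and macrophage markers held 0.00192% of counts in HAS2_Tg and 0.0809% in Has2_KO, and moved with this list. Interferon-stimulated genes rose in 13 of 40 cases and fell in 7 (camera adjusted p = 0.289), with Ifit3 at 0.77, Ifit2 at 0.77 and Oasl1 at -1.45. Antigen presentation genes rose in 6 of 15 cases and fell in 7 (camera adjusted p = 0.0903), with the class II genes Cd74 (-5.31), H2-Ab1 (-4.19) and H2-Aa (-3.79) among the latter, as were the macrophage markers.

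Cell cycle genes were lower in HAS2_Tg, 20 of 38, with 2 higher (median -0.52, camera adjusted p = 0.00796, and adjusted p = 0.0933 with an estimated correlation). The proliferation marker Mki67 was 3.16 ± 1.15 against 14.2 ± 0.81 CPM (-2.16), Rrm2 had -1.58 and Mcm6 -0.96. Macrophage (median -5.80) and endothelial (median -5.73) markers moved with the cell cycle list. Oxidative stress genes fell in 14 of 24 cases and rose in 4 (median -0.44, camera adjusted p = 0.0353, and adjusted p = 0.181 with an estimated correlation), with Prdx6 at -1.02, Hmox1 at -0.81 and Gsta4 at -0.81. The oxidative stress call ended without Has2_KO replicate 7 (adjusted p = 0.0542) or 8 (0.0694), over a range of 0.0171 to 0.0694 with each library left out. Cytosolic ribosomal protein genes rose in 37 of 81 cases and none fell (median 0.22, camera adjusted p = 0.00307, and adjusted p = 0.728 with an estimated correlation), led by Rpl30 (1.19), Rpl36 (0.53) and Rps19 (0.52), whose reads can be shared with pseudogene copies. With total counts this list's median was 0.04, so the size of the rise depends on scaling. The share of counts of these ribosomal protein genes was 5.01% in HAS2_Tg and 4.88% in Has2_KO (exact permutation p = 0.8). HAS2_Tg replicates 4, 5 and 6 held 5.43%, 4.78% and 4.81%.

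Lists of glycolysis (6 up, 6 down of 20), cholesterol synthesis (7 and 2 of 23), retinoid metabolism (8 and 4 of 20), endoplasmic reticulum stress (5 and 4 of 27), p53 targets (8 and 6 of 21) and immediate early and dissociation genes (9 and 11 of 30) did not pass, with camera adjusted p from 0.206 to 0.624. Their medians lay between 0.02 and 0.13 and changed sign with total counts, as that of the interferon list did. The glycolysis and retinoid lists had negative means, as did the immediate early list, whose test direction was down. Single members still differed, with the kinase gene Pfkp at 1.25 and Pdk1 at -1.77 in glycolysis, Bco1 at 1.52 and Rdh10 at -1.58 in retinoid metabolism, and Sc5d at 0.45, Pmvk at 0.53 and Insig1 at -0.35 in cholesterol synthesis. Herpud1 had 0.55, Ddit3 0.49 and Dnajb9 -0.47 among stress genes, Cdkn1a 0.62, Plk2 -0.68 and Plk3 -0.96 among p53 targets, and Egr2 -1.77, Ier3 -1.45 and Junb -0.76 among immediate early genes. Adjusted over the list alone, counts were the same as over all genes except for Notch (14 down), activation (9 down), identity (22 up), Wnt (14 up), NF-kB (32 down), oxidative stress (5 up), immediate early (10 up), ribosomal protein (38 up) and portal fibroblast and vascular smooth muscle genes (7 up, 7 down).

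**Figure D1:**
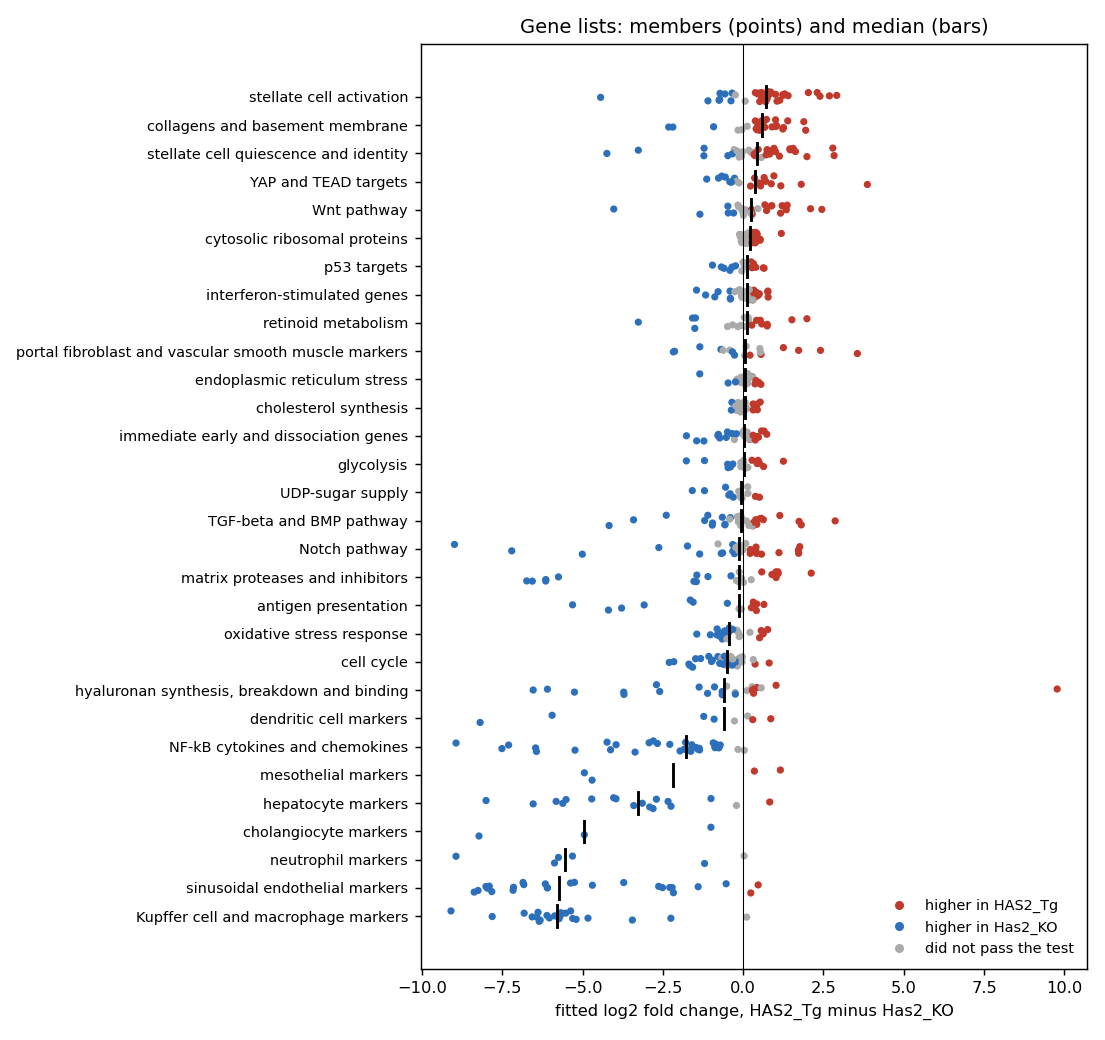
Fitted log2 fold changes (HAS2_Tg minus Has2_KO, x axis) of the members of each tested gene list (rows), with points for genes, coloured by edgeR call, and bars for list medians. Medians ran from -5.80 for the Kupffer cell and macrophage markers to 0.71 for the stellate cell activation genes.

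Most tested macrophage, sinusoidal endothelial, hepatocyte and neutrophil markers were higher in Has2_KO, while portal fibroblast and mesothelial markers split evenly. The low-count filter left 22 of 24 macrophage, 26 of 26 endothelial, 18 of 27 hepatocyte and 6 of 13 neutrophil markers listed in the files. Markers near 0 CPM in HAS2_Tg could pass it only through Has2_KO, so the filter partly fixed the direction among tested members. Of 22 Kupffer cell and macrophage markers 21 passed as lower in HAS2_Tg (median -5.80, camera adjusted p = 4.47e-73, and 0.00591 with an estimated correlation), with Lyz2 at 2.32 ± 0.35 against 190.3 ± 13.2 CPM (-6.35), Mpeg1 at -6.32 and Ctss at -5.69. Of 26 sinusoidal endothelial markers 24 were lower and 2, Eng and Gata4 (named after their values were seen), were higher (median -5.73, or -5.31 with genes absent from a group at their bound; camera adjusted p = 4.14e-82, and 0.00599 with an estimated correlation), with Mrc1 at -8.01. Of 18 hepatocyte markers 16 were lower and Ass1 (0.83) was higher (median -3.27, camera adjusted p = 1.24e-05, and adjusted p = 0.16 with an estimated correlation). Albumin, Alb, was 0.88 ± 0.31 against 23.4 ± 4.44 CPM, and Apob had a scaled ratio of 57.4 in favour of Has2_KO (95% exact interval 15.6 to 479). Of 6 neutrophil markers 5 were lower (median -5.53, camera adjusted p = 4.31e-07, and 0.0458 with an estimated correlation), with Clec4d at a scaled ratio of 65.3 (22.1 to 319) and Hdc at -5.32.

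Of 13 cholangiocyte markers 3 were tested, and Krt8 and Krt18, near 0 CPM in HAS2_Tg, could pass the filter only through Has2_KO. The 3 tested, Krt8, Krt18 and Sox9, were all lower (camera adjusted p = 0.0173, and adjusted p = 0.233 with an estimated correlation), Krt18 by at least 34.5-fold. This call ended without HAS2_Tg replicate 4 (adjusted p = 0.0563; range 0.00545 to 0.0563 with each library left out). Dendritic cell markers were lower in 4 of 8 cases and higher in 2 (median -0.59, camera adjusted p = 0.00681, and adjusted p = 0.118 with an estimated correlation), with Itgax at a scaled ratio of 326 (111 to 1582), Irf8 at -1.23 and Fscn1 at -0.91. Portal fibroblast and vascular smooth muscle markers split 6 and 6 of 18 (median 0.07, which turned negative with total counts; camera adjusted p = 0.0167, and adjusted p = 0.118 with an estimated correlation), with Lmod1 at 2.41 beside Myh11 and Notch3. Mesothelial markers split 2 and 2 of 4 (camera adjusted p = 0.273), with Wt1 at -4.70 and Efemp1 at 0.35. Efemp1 did not pass with total counts (0.17, edgeR adjusted p = 0.0906) or in the FPKM fits, so this split depends on scaling. T and NK (Il7r lower, Cd8b1 0.42), B and plasma cell (Cd22 -1.20, Cd37 lower) and erythroid (Tfrc -0.34) lists had 2, 2 and 1 tested members and no list test. The Cd8b1 call ended with total counts (edgeR adjusted p = 0.175), with the DESeq2 Wald test (adjusted p = 0.139) and in further alternatives. The endothelial markers took 0.127% of counts in HAS2_Tg and 0.258% in Has2_KO and the macrophage markers 0.00192% and 0.0809% (exact permutation p = 0.1 for each, the smallest that 3 against 3 allow). The endothelial share differed by a factor of 2.03, far less than that list's median log2 fold change of -5.73. Eng and Gata4, which were higher in HAS2_Tg, count towards the share, so it does not stand for most members. Shares were higher in HAS2_Tg for hepatocyte markers, at 0.0451% against 0.0361%, opposite to that list's median, and for portal fibroblast and vascular smooth muscle markers, at 0.28% against 0.169% (exact permutation p = 0.1 for each). Most of the hepatocyte share came from Ass1 (453 CPM in HAS2_Tg, 255 in Has2_KO). Most of the portal fibroblast and vascular smooth muscle difference came from Myh11 (1270.4 and 108 CPM). Dendritic cell markers took 0.0701% and 0.067% (exact permutation p = 0.7) and mesothelial markers 0.0271% and 0.0248% (exact permutation p = 0.3).

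**Figure D2:**
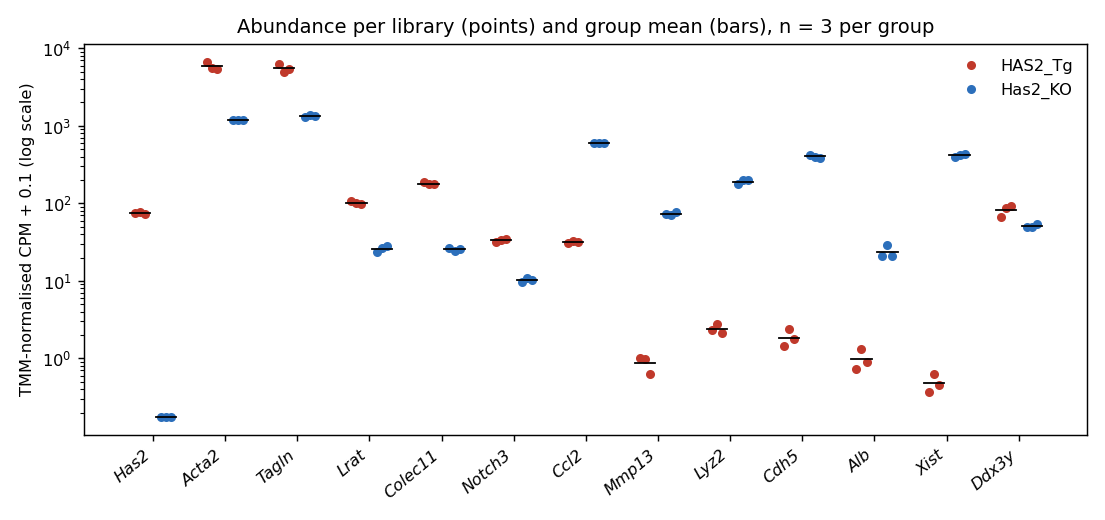
TMM-normalised CPM plus 0.1 (y axis, log scale) of 13 genes (x axis), with points for the 3 libraries of each group and bars for group means. Acta2 averaged 5904 CPM in HAS2_Tg and 1196 in Has2_KO, and Lyz2 2.32 and 190.3.

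Xist, the transcript of the inactive X chromosome, was 0.38 ± 0.13 CPM in HAS2_Tg and 417 ± 19.2 CPM in Has2_KO (SD, n = 3; log2 fold change -10.06, SE 0.15, edgeR adjusted p = 3.58e-15), although the labels describe all mice as male. Its antisense partner Tsix was at least 198-fold lower in HAS2_Tg, and without strand information their reads cannot be separated. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were present in all 6 libraries and stood in Has2_KO at 0.615, 0.604, 0.661 and 0.578 of their HAS2_Tg level. These 4 genes were chosen after their values were seen.

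The direction split of the calls depended on scaling: with total counts 1477 genes were higher and 4827 lower in HAS2_Tg, and with limma on log2(FPKM + 1) 1399 and 4198. Total counts shifted the median log2 fold change by -0.17 against the reported fit. The labels do not say whether replicates were separate animals, so p-values measure the spread between these libraries, which may be technical; the common biological coefficient of variation was 0.109 in HAS2_Tg and 0.043 in Has2_KO.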

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

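No paired analysis was possible because the groups share no replicate numbers. Fits without sex chromosomes, marker-list genes or pseudogenes were chosen after seeing the data, and the cause of the differences below was not tested unless stated. Across 18 alternatives, the 110 named genes gave 1899 of 1916 values with the direction and side of the threshold of the reported fit, and 17 values in 5 genes (among them Mup19, Cd8b1, Efemp1 and Tfrc) kept the direction without passing; no named gene reversed. Has2 passed in each of them. Most named genes were picked for large changes or small adjusted p in the reported fit, so they do not stand for the other calls. Of the 5298 calls, 4150 were also made with total counts and 3670 with limma on log2(FPKM + 1), which tests fewer genes. Calls numbered 4188 to 5624 with each library left out and 3729 at an adjusted p of 0.01, but 1597 against a fold of 1.5, a stricter null. Genes higher and lower in HAS2_Tg numbered 1477 and 4827 with total counts, 1399 and 4198 with limma on log2(FPKM + 1), 1376 and 4138 with log2(FPKM + 0.1), and 1366 and 4596 with no filter on FPKM. Changes of at least 2-fold numbered 756 with the stricter filter, which tests fewer genes, 786 with limma on log2(FPKM + 1) and 798 with no filter on FPKM. Of 30 lists tested, 18 passed, 10 without marker-list genes, a fit in which the 8 marker lists have no value, and 6 with an estimated correlation. Too few members were left to test cholangiocyte, mesothelial and neutrophil markers under the stricter filter and cholangiocyte markers in the filtered FPKM fits.

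With an estimated correlation, adjusted p was 0.0844 for activation, 0.16 for collagens, YAP targets and hepatocyte markers, 0.0933 for proteases and cell cycle, 0.0902 for Wnt, 0.181 for oxidative stress, 0.233 for cholangiocyte, 0.118 for dendritic and portal fibroblast markers and 0.728 for ribosomal proteins. With limma on log2(FPKM + 1), log2(FPKM + 0.1) and no FPKM filter, in that order, adjusted p was 0.0885, 0.129 and 0.0785 for hyaluronan, 0.538, 0.714 and 0.486 for proteases, 0.496, 0.435 and 0.579 for dendritic, and 0.116, 0.129 and 0.0783 for portal fibroblast markers. Retinoid genes passed in the first pair (0.0455 and 0.0449), UDP-sugar genes with no FPKM filter (0.0311), and cholangiocyte markers were at 0.576 there. Without a low-count filter, p was 0.0989 for cholangiocyte and 0.1155 for dendritic and portal fibroblast markers, and with DESeq2 0.104 and 0.27 for the first pair. The stricter filter left hepatocyte markers at 0.317, and hyaluronan genes were at 0.166 without marker-list genes. By fry, which does not compare a list with other genes, UDP-sugar (0.00102), Notch (0.0474), antigen presentation (0.0014), immediate early (0.0395) and mesothelial genes (0.00199) passed and ribosomal proteins did not (0.0537). With each library left out, oxidative stress ranged from 0.0171 to 0.0694 and cholangiocyte markers from 0.00545 to 0.0563. At these depths the simulation recovered 22% of genes changed 1.25-fold, so small changes can be missed. It changed only 200 genes, where the data gave 5298 calls. The adjusted threshold was therefore stricter in the simulation, and the share recovered in the data may differ.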

Other observations

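The count of splits and the test of the region around Has2 were set before the data were examined; the tests on other cell types, on Xist and Y-linked genes and on pseudogenes were chosen, with their bounds, after those results were seen, as were the genes named in them that the fixed rule does not take.

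Of the 10 splits of the 6 libraries into 3 and 3, 1, the genotype split, gave as many as 5298 calls. The highest of the others gave 0. Each of the others put libraries of both genotypes in both groups, where the genotype difference adds to the spread within groups. Few calls were therefore likely in them whatever the cause, and 10 splits are too few for a share under 0.05. Near Has2, 20 of 45 tested genes within 10 Mb were called (44.4%) against 5269 of 12939 elsewhere (40.7%), with a two-sided Fisher's exact p of 0.65, and the 45 genes are too few to decide whether passenger genome around the locus adds calls. Genes there with changes of at least 2-fold include Colec10 (2.79) and Col14a1 (1.39).

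Macrophage and endothelial markers were higher in Has2_KO, beside lower Acta2 and Lrat and higher Ccl2. Dilution of stellate RNA alone, a first hypothesis, would lower the stellate genes by 1 common factor, but the interquartile range of log2 fold changes over the identity list, 1.10, was 12.1 times the median SE, and Reln had -0.01 where Colec11 had 2.83. Members that other liver cells also express need not share 1 factor. The list holds Gata4, also on the endothelial list, and Plvap, written down as endothelial too. The wide range therefore does not exclude dilution as a part of the change. Per the labels, macrophages were removed with Cd11b microbeads, but how completely is not given, and that step was not for endothelial cells. RNA of other liver cells in the Has2_KO libraries may account for the markers themselves. Of 15 tested macrophage and endothelial genes outside the fixed lists, 14 (93.3%) were called at least 2-fold higher there. Lcp1 at 88.2 CPM and Laptm5 at 47.2 CPM were among them. Each of the 14 had at most 2.44 CPM in HAS2_Tg, so most were tested only because of their Has2_KO level. Their share therefore does not decide the question. The exception, Ecscr, was the 1 gene of the 15 above 5 CPM in HAS2_Tg, and 14 of 30 names first written down were left out because a fixed list held them. Among the names left out, Plvap (1.46) was also higher in HAS2_Tg. All the others were lower there, Ramp2 (-0.53) by under 2-fold. An effect of genotype on these cells stays open and untested, as does the source of the NF-kB, protease and cell cycle transcripts, because every Has2_KO library carries the markers.

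Xist stood beside Y-linked transcripts in Has2_KO. Male cells alone are argued against by Xist, at least 1042 times the HAS2_Tg mean in each Has2_KO library, and female cells alone by the Y-linked genes, at a median of 0.61 of their HAS2_Tg level. Male and female cells together in each Has2_KO library may account for both, because the 4 Y-linked ratios lay within a factor of 1.084 of their median. Kdm6a (-0.56), Eif2s3x (-0.48), Ddx3x (-0.44) and Kdm5c (-0.21), X-linked genes that escape inactivation, were also lower in HAS2_Tg. Sex and genotype would then be confounded, because each Has2_KO library had high Xist and no HAS2_Tg library did. Without genes of the sex chromosomes 5115 calls were made, but that fit keeps any effect of sex on autosomal genes.

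Atp6v0c, a proton pump subunit gene on chromosome 17, and its pseudogene Atp6v0c-ps2 on chromosome 6 moved in opposite directions. The pseudogene had 0.12 CPM in HAS2_Tg and 222.5 in Has2_KO (log2 fold change -10.77), and the gene 250.8 and 49.1 (2.35). Their summed CPM had a log2 ratio of -0.114, HAS2_Tg over Has2_KO, so reads of 1 gene assigned to another copy in each group may account for the pair, and a strain variant that decides the copy stays open, untested without reads. Whether other copies share this stays open: of 5 copies called at least 2-fold with a tested parent, 1 showed a conserved sum and a parent that itself passed the test in the other direction, and 3 did when the parent needed only the opposite sign. Rpl34-ps1, at 36.5 against 0.63 CPM, had a parent, Rpl34, at -0.06.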
